A study of Anopheles gambiae with 3 samples.

How the data were processed

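Expression was measured on Affymetrix GeneChip arrays in whole bodies of adult females of the pink-eye strain of Anopheles gambiae, a mosquito that transmits malaria. All 3 samples belong to 1 group, females that took 2 blood meals within a single gonotrophic cycle, the interval between taking blood and laying eggs. The mosquitoes were fed on anaesthetized mice at 4 days of age and offered mouse blood again 48 h later. They were collected 24 h after the later meal, which is 72 h after the earlier one. Each sample was a pool of 5 females, described in the labels as a biological sample, so the 3 arrays cover 15 mosquitoes. Per the labels' protocols, 10 µg of total RNA was copied into double-stranded cDNA from oligo(dT) primers carrying a T7 promoter and transcribed into biotin-labelled cRNA, of which 15 µg was fragmented. Priming at the poly(A) tail favours the 3' part of transcripts.

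The deposited values are probe set intensities on a linear scale, 1 column per array, and the authors kept the 3 arrays separate. GCOS version 1.1.1, Affymetrix's array software, is named in the submitters' processing notes. The summarisation method, probe masking and annotation are not given in the sources used here. In each column the mean of all probe sets, after trimming 2% at each end, was 500.3, so the deposited intensities had been scaled to a common mean per array. No detection calls or raw scanner values were used here. For arrays, the number of replicates limits the precision, and no counting depth applies.

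The 22761 probe sets were sorted by the prefix of their IDs. There were 16884 with the prefix Ag. and 4502 with the prefix Pf. These prefixes were read as the mosquito and the Plasmodium parts of the array, as the named control probe sets for actin and Gapdh use them. A further 144 IDs began with AFFX (controls, 52 of them with the prefix AFFX-AgPf), 941 began with a sequence accession and 290 with a bare number. The Ag. IDs carry a chromosome arm (2L, 2R, 3L, 3R, X or UNKN), a cluster number and, for most, CDS or UTR, read here as coding sequence and untranslated region. They carry no gene name. Neither the table nor the reference table of 15165 genes pairs Ag. IDs with genes, and 0 of 457 sequence accessions in the IDs matched the reference. The 43 gene lists fixed before the data were examined (among them yolk, blood digestion, immunity, detoxification and markers of hemocytes, sperm and salivary glands) could therefore not be tested. The genes to be named could not be identified either. The groups given by the IDs (6 arm labels and 3 transcript part labels), chosen after the IDs had been seen, took the place of the lists. Genome coordinates are not printed, since the build behind the IDs is not given in the sources used here.

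Because no label names a parasite, the Pf. probe sets served as background. A mosquito probe set was called detected when its intensity exceeded the 95th percentile of the Pf. probe sets of the same array in all 3 arrays. Intensities were put on the log2 scale without a pseudocount, and each array was centred on its median over the detected probe sets. The spread of a probe set is the SD of these values over the 3 pools. Detected shares of ID groups were tested with Fisher's exact test, two-sided. The median spread of each group, and its median deviation in each pool, were set against 10000 random lists of the same size matched on mean level in 20 bins, two-sided. All families were adjusted by Benjamini-Hochberg (9 tests of detected share, 9 of spread and 27 of deviation, with a threshold of 0.05). Tests among named arms were adjusted over the 5 arms, for each transcript part separately where parts were tested alone. Probe sets with the same arm and cluster number were paired, the 2 first by ID in each cluster, and the mean correlation of their deviations over the 3 arrays was compared with 10000 random re-pairings, one-sided. Probe sets are not independent replicates, so these p-values describe the arrays at hand. No comparison between conditions was possible with 1 group, and p-values on shifts of a single pool test no condition.

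The planned rule for naming features asked for listed genes and for the 10 probe sets with the largest spread. Without gene names, 3 of those 10 are printed by ID (1 with its odd pool above the other pools, 2 below), together with the brightest Pf. probe set and the named controls. The odd pool of a probe set is its highest or lowest pool, whichever lies farther from the middle one in centred log2 values. This rule names 1 pool for every probe set, also where the 3 pools are nearly evenly spaced. Alternatives were the 90th and 99th percentiles as background, detection in any 2 arrays, no centring, quantile normalization, log2(intensity + 50), no detection filter with a floor of 1, omission of probe sets with _s_ or _x_ in the ID, cluster means, and leaving out each replicate. Tests on named arms alone, on pairs by level class and on pairs by suffix letter or transcript part were added after seeing the data. Data were simulated with the levels of the 12167 detected probe sets. In 1 pool a list was moved to deviate by 0.05 log2 from its mean over pools, and its SD was multiplied by 1.2. Its shift was called in 20 of 20 simulated data sets, and that of an unshifted list in 1 of 20. These simulations used the same SD at every level and independent noise, unlike the arrays. They do not give the power for smaller shifts. With 2600 simulated probe sets in pairs, 20% shared variance was called in 20 of 20 data sets and recovered as 20.4%, and 0% was called in 0 of 20. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.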

Results

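The data set held whole-body expression profiles of Anopheles gambiae females after a repeated blood meal within a gonotrophic cycle, as 3 pools of 5 mosquitoes with 1 array each. All pools had the same treatment and no control group was analysed here. The questions the design allows are which transcripts were measurable at 72 h after the earlier meal and how closely the replicate pools resembled each other. The median intensity of mosquito probe sets was 303.2 in pool 1, 292.5 in pool 2 and 301.7 in pool 3. The median of the Plasmodium probe sets was 9.32, 9.48 and 12.1 in the same pools.

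Most of the mosquito part of the array gave signal above the Plasmodium background. Of 16884 mosquito probe sets, 12167 (72.1%) lay above the background of the Plasmodium probe sets in all 3 pools. The background cut-off was 57.4 in pool 1, 51.8 in pool 2 and 64.4 in pool 3. In single pools, 13116 (77.7%), 13255 (78.5%) and 13059 (77.3%) mosquito probe sets passed it. By the definition of the cut-off 226 Plasmodium probe sets passed it in each pool, and 77 of 4502 (1.71%) passed it in all 3. Some other controls passed it in all 3 more often, 6 of 17 with Tag in the ID and 4 of 14 with HUM, HSAC or hum in the ID. HUMGAPDH probe sets were among those 4, and whether they match mosquito Gapdh was not tested. None passed it in all 3 among the 7 Plasmodium actin and Gapdh and the 3 fluorescent marker controls. The 1.71% is therefore no measure of false detection among mosquito probe sets.

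The mosquito transcripts that the probe set IDs name were bright in every pool, and Gapdh varied more than actin at its 3' end and middle. Actin, a protein of the cytoskeleton, was covered by 3 mosquito probe sets. Their intensities were 12856 ± 1547 (SD, n = 3) at the 5' end, 21359 ± 1201 in the middle and 16677 ± 1165 at the 3' end. Gapdh, an enzyme of glycolysis, gave 11504 ± 344 (SD, n = 3) at the 5' end, 22499 ± 4051 in the middle and 23537 ± 5564 at the 3' end. All 6 mosquito controls were above background in all 3 pools. The coefficient of variation between pools ran from 5.62% to 12.0% for actin and from 2.99% to 23.6% for Gapdh. On the log2 scale the SD was 0.36 for the 3' and 0.28 for the middle Gapdh probe set, above the 0.25 that bounded 90% of the brightest of 10 level classes of detected probe sets, and between 0.08 and 0.19 for actin.

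Controls for parasite actin and Gapdh and for fluorescent markers stayed near background. None of the 3 probe sets for Plasmodium actin passed the cut-off in any pool, with intensities between 1.07 and 31.3. Of the 4 for Plasmodium Gapdh, 3 passed it in a single pool each and 0 in all 3, with intensities of at most 98.6. The enhanced green fluorescent protein (EGFP) marker, a reporter used in transgenic insects, read 26.3 ± 3.87 (SD, n = 3) and passed the cut-off in 0 pools. The red fluorescent markers AsRed2 (58.6 ± 9.15) and DsRed-Express (46.2 ± 22.4) each passed it in 1 pool. Of all 52 controls with the prefix AFFX-AgPf, which include these markers, 9 lay above the cut-off in all 3 pools.

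**Figure D1:**
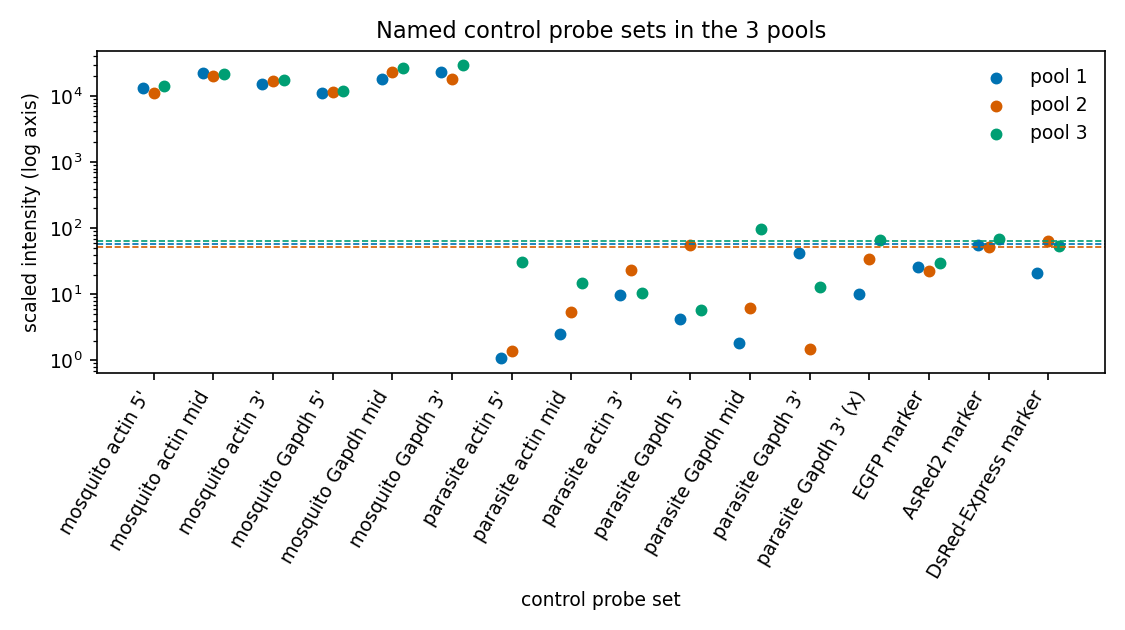
Scaled intensity (log axis) of named control probe sets, 1 point per pool, with dashed lines at the background cut-off of each pool (57.4, 51.8 and 64.4). The 6 mosquito actin and Gapdh probe sets lie between 11106 and 29228, and the parasite and fluorescent marker probe sets lie at or below 98.6.

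The 18 probe sets for the bacterial bioB, bioC and bioD and the phage cre spikes, which are added to check hybridization, were above background in all pools with coefficients of variation from 4.49% to 18.4%. Of the 27 probe sets for Bacillus transcripts (dap, lys, phe, thr and trp), 22 were above background in all pools, and the coefficients of variation of the 27 ran from 5.04% to 63.1%. The 3' over 5' ratio of a transcript within an array, a common reading of RNA integrity and labelling, was compared between pools. For mosquito actin this ratio was 1.15 in pool 1, 1.52 in pool 2 and 1.26 in pool 3, a mean log2 ratio of 0.38 ± 0.21 (SD, n = 3). For mosquito Gapdh it was 2.08, 1.58 and 2.46, a mean log2 ratio of 1.01 ± 0.33 (SD, n = 3). Pool 2 thus had the highest ratio for actin and the lowest for Gapdh.

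Detection differed with the transcript part marked in the probe set ID. Probe sets marked UTR were detected most often, 759 of 790 (96.1%), against 70.9% of all other mosquito probe sets (Fisher's exact test, odds ratio 10.1, adjusted p = 1.00e-71). Those marked CDS were detected less often, 9766 of 14060 (69.5%), against 85.0% of the rest (Fisher's exact test, odds ratio 0.40, adjusted p = 2.24e-69). Those with neither mark lay between, 1642 of 2034 (80.7%). The groups were not compared within clusters, so the transcript part was not separated from which genes have a UTR probe set.

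Transcripts of unknown place stood apart from those of the named chromosome arms. Only 780 of 1938 probe sets marked UNKN (40.2%) were detected, against 76.2% of the rest (Fisher's exact test, odds ratio 0.21, adjusted p = 1.09e-214). The share was 77.0% on 2L, 76.9% on 2R, 76.0% on 3L, 75.7% on 3R and 73.2% on X. Against all other mosquito probe sets the 4 autosomal arms passed Fisher's exact test (adjusted p from 3.36e-17 to 2.13e-06) and X did not (odds ratio 1.06, adjusted p = 0.34). Among the 5 named arms alone, a comparison added after seeing the data, none of the 4 autosomal arms passed, with odds ratios from 0.97 to 1.06, and X did.

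X chromosome probe sets were detected less often than those of the other named arms, 1027 of 1403 (73.2%) against 76.5% (Fisher's exact test, odds ratio 0.84, adjusted p = 0.031). The difference was 11.1 percentage points for probe sets with neither mark (71.9% against 83.0%, Fisher's exact test, adjusted p = 0.00083). For CDS probe sets it was 2.25 percentage points (805 of 1118 on X against 74.3% elsewhere, Fisher's exact test, adjusted p = 0.52), and for UTR probe sets the share was 97.1% on X and 96.2% elsewhere (adjusted p = 1). Without pool 2 the overall X comparison no longer passed (Fisher's exact test, adjusted p = 0.12).

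**Figure D2:**
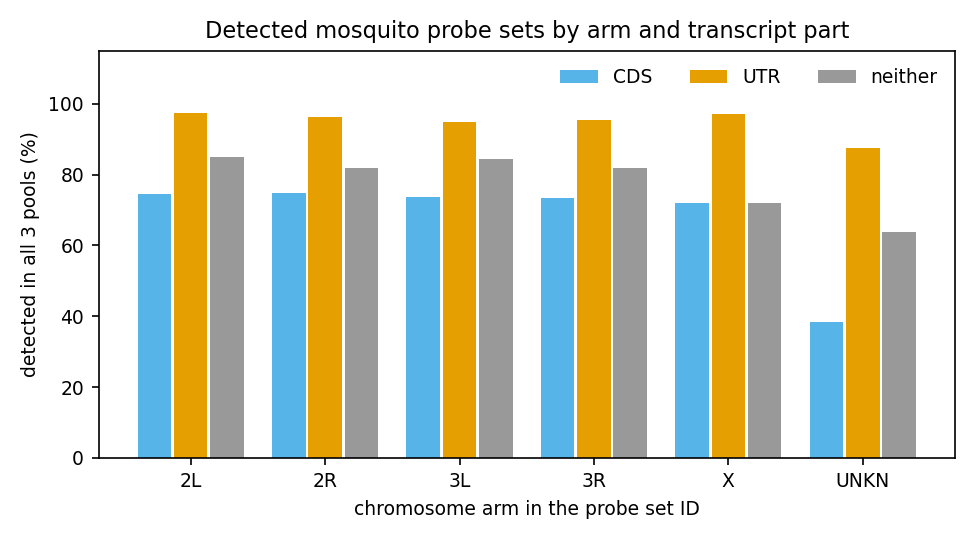
Share of mosquito probe sets detected in all 3 pools (%), by chromosome arm and by the transcript part in the ID (bars for CDS, UTR and neither). UTR bars lie at 87.5% or above for every arm label, and the CDS bar of UNKN, at 38.3%, is the lowest.

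Detected transcripts had similar levels in the replicate pools. Across the 12167 detected probe sets, the correlation of log2 intensities was 0.977 between pools 1 and 2, 0.975 between pools 1 and 3 and 0.977 between pools 2 and 3. Across the Plasmodium probe sets it was 0.41, 0.40 and 0.40. These are correlations across probe sets, which are not independent replicates. The median SD between pools was 0.17 log2 and 90% of detected probe sets had an SD below 0.42.

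The spread fell with level. In the dimmest of 10 level classes of about equal size, with mean levels from 60.9 to 130.2, the median SD was 0.34 log2. In the brightest class, at 2776 or more, it was 0.12. Differences of more than 2-fold between 2 pools were seen for 288 probe sets (2.37%) between pools 1 and 2. Between pools 1 and 3 there were also 288, and between pools 2 and 3 there were 309 (2.54%). An SD above 0.5 log2 was found for 741 probe sets (6.09%) and an SD above 1 for 22. The latter count was 60 to 67 without any 1 of the pools, 5 with the 99th percentile cut-off, 8 with log2(intensity + 50) and 1455 without the detection filter. An SD of 2 pools takes large values more often than an SD of 3, so the counts without a pool are not comparable with 22.

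**Figure D3:**
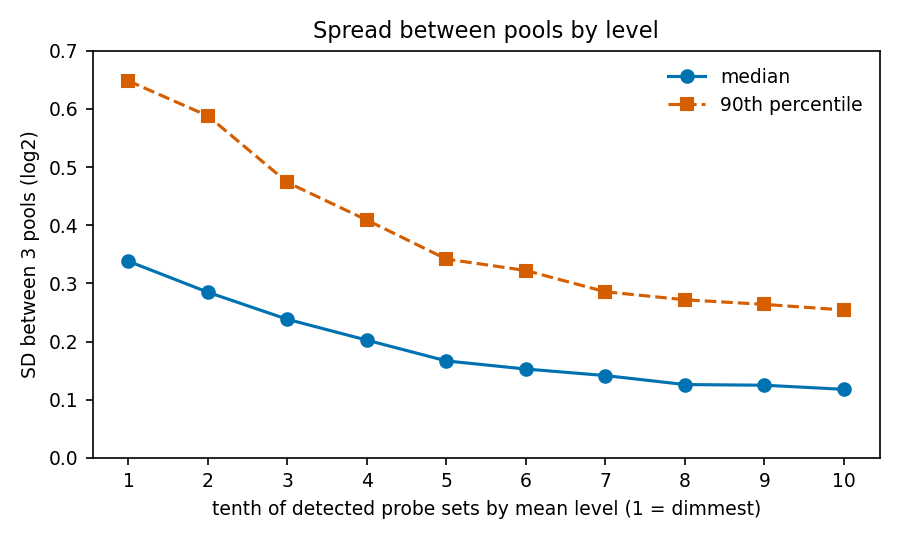
SD between the 3 pools (log2) against 10 classes of the detected probe sets ordered by mean level, as the median (circles) and 90th percentile (squares) of each class. The median falls from 0.34 in the dimmest class to 0.12 in the brightest.

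The transcripts that differed most between pools were mostly ones close to background in a pool. The probe set with the largest spread, Ag.2R.1704.0_CDS_at, read 1676 in pool 1, 405.2 in pool 2 and 79.0 in pool 3, an SD of 2.19 log2. Ag.3R.1860.0_CDS_at read 819.0, 340.2 and 75.0, an SD of 1.73 log2. Ag.3R.2469.0_CDS_at was higher in pool 1 (314.0) than in pools 2 (53.5) and 3 (89.8), with an SD of 1.30 log2. Among the 10 probe sets with the largest spread, the odd pool lay below the other pools for 9, and for 9 the lowest pool was within 2-fold of the cut-off. An odd pool is named even where the 3 pools are nearly evenly spaced in log2, as for Ag.2R.1704.0_CDS_at. With 1 array per pool, these differences between single pools have no replicate check. The SD of Ag.2R.1704.0_CDS_at was 1.44 log2 without pool 3 and 3.09 without pool 2. That of Ag.3R.1860.0_CDS_at was 0.89 without pool 3 and 2.41 without pool 2, and that of Ag.3R.2469.0_CDS_at was 0.55 without pool 1 and 1.80 without pool 3.

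Probe sets of the same cluster deviated together between pools. In 1327 clusters with at least 2 detected probe sets, the mean correlation of the deviations over the 3 pools was 0.133, against a mean of 0.0062 in random re-pairings (permutation test, one-sided, p = 0.0001, the smallest that 10000 re-pairings can give). The variance shared by the 2 probe sets was 17.7% of the total between pools. With the pairs divided by level into 3 classes, it was 14.0% in the 443 dimmest pairs, 14.7% in the 442 of middle level and 35.7% in the 442 brightest, with levels of 1060.2 or more. The mean correlation in these classes was 0.095, 0.064 and 0.24 (permutation test, one-sided, p = 0.0056, 0.027 and 0.0001), and that of the middle class lay inside the central 95% of its re-pairings (-0.067 to 0.065). In 44 pairs whose first member had an SD above 0.5 log2 it was 0.14 (p = 0.20, permutation test). In 403 pairs without any suffix letter in their IDs the mean correlation was 0.042 (p = 0.13, permutation test). In 674 pairs of a CDS and a UTR probe set it was 0.131 (p = 0.0001, permutation test).

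UTR probe sets shifted between pools by small amounts. They lay lower in pool 1, with a median deviation of -0.039 log2 against -0.015 in random lists matched on level, and higher in pool 2, at 0.016 against -0.0052 (permutation test, both adjusted p = 0.0018). Probe sets with neither mark were lower in pool 1 (-0.022 against -0.0043, adjusted p = 0.0040, permutation test). CDS probe sets make up 9766 of the 12167 from which the random lists were drawn. Their higher value in pool 1 (0.0021 against -0.0027, adjusted p = 0.0018, permutation test) therefore mirrors the other groups and is no separate result. The actin 3' over 5' ratio was lowest in pool 1 (1.15) and highest in pool 2 (1.52), whereas that of Gapdh was lowest in pool 2. None of the 18 deviations of the arm labels passed the test, the smallest adjusted p being 0.12 for 3R in pool 3, and 1 of 18 had an unadjusted p below 0.05. None of the 9 groups had a spread between pools that differed from matched random lists after adjustment, and 1 of 9, 3L, had an unadjusted p below 0.05 (0.026).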

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

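The test on Plasmodium controls, the test of the whole array's scale, the comparison of background under an equal filter, the omission of the bright probe set from the test by suffix letter of Plasmodium probe sets and the comparison by suffix letter within level classes were chosen after the values had been seen, and the tests on pairs by suffix letter, level or transcript part were added after the data had been examined.

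A single Plasmodium probe set, Pf.6.239.0_CDS_s_at, was bright in data outside the mosquito measurement, at 3152 in pool 1, 3133 in pool 2 and 3195 in pool 3, a mean of 3160, where the Plasmodium medians were 9.32, 9.48 and 12.1. It was the only one of 4502 above the Plasmodium median by more than 3 scaled median absolute deviations in all pools (760.4, 671.7 and 968.9 were needed). At 5 deviations 0 passed, a limit of 14298, 11499 and 18024 that only 166 of the array's 22761 probe sets exceeded in all pools. Parasite RNA in the pools is argued against by the named Plasmodium actin and Gapdh controls, of which 0 of 7 lay above the cut-off in all 3 pools. Probes that match a mosquito transcript are a candidate explanation, since the other Plasmodium probe sets with _s_ or _x_ in the ID passed the cut-off in all pools more often than those without (10 of 312 against 66 of 4189, Fisher's exact test, odds ratio 2.07, p = 0.040), but its target was not identified and no biological explanation was tested.

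Plasmodium probe sets as a class were brighter in pool 3, by a median of 0.32 log2 against the mean of the other pools. Other dim classes had their highest median there too, at 12.3, 11.2 and 15.9 in pools 1 to 3 for accession-named probe sets and 25.2, 27.3 and 32.3 for AFFX-AgPf controls. To examine a higher scale of the whole array, the shift was compared with that of the detected mosquito probe sets. The difference was 0.32 log2 (95% bootstrap interval 0.26 to 0.37). Each array had already been scaled to a common mean, which largely fixed the mosquito shift (0.0045 log2) beforehand. The comparison therefore cannot decide whether a larger scaling factor raised the dim probe sets of pool 3. An additive background stays open, because its test depended on the matching and on a correction. The shift of dim mosquito minus Plasmodium probe sets was 0.49 intensity units (0.085 to 0.91) under an equal filter. It was 0.34 (-0.086 to 0.77) after the mean over choices of the odd pool was subtracted. With the same subtraction it was -3.85 (-5.18 to -2.23) within bins of a mean level that includes pool 3. A background that differs between probe sets stays open as well, and no biological explanation was tested.

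The agreement of probe sets of the same cluster between pools was weighed against shared probes. A level-dependent difference between arrays is argued against, since the central 95% of re-pairings within bins of level ended at 0.056, below the observed 0.133. A difference in 3' labelling common to all transcripts is argued against by the CDS with UTR pairs, whose mean correlation of 0.131 was above the 0.062 of re-pairings. A labelling difference that varies between transcripts could move both probe sets of a pair together, so these pairs cannot decide on it. Probes shared between probe sets of a cluster remain a candidate explanation. Pairs without a suffix letter had a mean correlation of 0.042, inside the range of re-pairings (-0.066 to 0.070). Their shared variance was 9.46%, against 17.7% over all pairs. Within level classes, pairs with a suffix letter exceeded those without by 0.12 (permutation test, two-sided, p = 0.0058). The 0.131 of CDS with UTR pairs cannot decide on shared probes, though those marks are read as different parts of a transcript. There were 674 such pairs and only 403 clusters with a pair without a suffix letter. Some CDS with UTR pairs therefore carry such a letter, and they were not split by it. Which probes the sets share was not known. The 3 pools are a single treatment group, so no biological explanation was tested.

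Of the array's other classes, 109 of 941 accession-named probe sets and 54 of 290 number-named probe sets lay above the cut-off in all 3 pools. A control probe set of the AFFX-AgPf class had a mean of 23041 ± 3208 (SD, n = 3).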

How the results depend on the processing

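Tests on named arms alone, on X among them and on pairs by level, suffix letter or transcript part were chosen after seeing the data. The count of 12167 detected probe sets stayed within 1.5 times under every alternative run, and between 12419 and 12561 without a replicate. No paired analysis was possible because there was 1 group. The median SD of 0.17 log2 became 0.15 with log2(intensity + 50), 0.16 with the 99th percentile cut-off and 0.23 with no detection filter and a floor of 1, and 0.137 to 0.144 without a replicate. The 22 probe sets with SD above 1 became 8, 5 and 1455 under the same 3 settings, and 60 to 67 without a replicate. An SD of 2 pools tends to have a lower median and more large values than an SD of 3. The median SD and the count without a replicate therefore do not show dependence on a pool. By signal over background, the median SD was 0.34 log2 in the dimmest and 0.12 in the brightest of 10 level classes. The mean correlation within clusters lost its call in pairs without any suffix letter (0.042) and in the 44 pairs whose first member had an SD above 0.5 (0.14, p = 0.20, permutation test). It passed at 0.064 in pairs of middle level (one-sided permutation p = 0.027), though inside the central 95% of re-pairings. Without a replicate, 52.4% to 56.7% of pairs deviated the same way. All 9 detected shares kept direction and side at the other cut-offs and without a replicate. Without a replicate the odds ratios ran from 1.39 to 1.41 (2L), 1.39 to 1.45 (2R), 1.26 to 1.27 (3L), 1.23 to 1.27 (3R), 1.05 to 1.09 (X), 0.215 to 0.220 (UNKN), 0.38 to 0.40 (CDS), 9.31 to 13.0 (UTR) and 1.73 to 1.83 (neither). At the 99th and 90th percentile cut-offs they were 1.38 and 1.38 (2L), 1.39 and 1.42 (2R), 1.23 and 1.29 (3L), 1.21 and 1.24 (3R), 1.06 and 1.06 (X), 0.198 and 0.223 (UNKN), 0.428 and 0.378 (CDS), 8.27 and 12.4 (UTR) and 1.60 and 1.82 (neither). Among named arms alone the odds ratios were 1.06 (2L), 1.06 (2R), 0.99 (3L, reversed), 0.97 (3R, reversed) and 0.84 (X, reversed and called), since UNKN probe sets were left out of the reference. For X among named arms they ran from 0.82 to 0.86 without a replicate, with 0.89 in CDS and 1.31 in UTR probe sets (reversed). At 3 scaled deviations 1 Plasmodium probe set passed in place of 0 at 5, and 0 passed at 5 without any of the replicates, at a limit that 166 of 22761 probe sets of all classes exceeded. No spread of an ID group was called under any setting, and directions changed for several uncalled values, given as differences in log2 from random lists. They were 0.00098 (2R), -0.00098 (3R) and 0.0028 (UTR) with quantile normalization, -0.00064 (X) with the 99th percentile cut-off and -0.00077 (X) with cluster means. Without a replicate these ran from 0.0016 to 0.0058 (2L), -0.0017 to -0.0012 (2R), -0.0098 to 0.00060 (3L), -0.0021 to 0.0019 (3R), 0.0030 to 0.0070 (X), -0.0067 to 0.015 (UNKN), -0.0013 to 0.00034 (CDS), -0.0027 to 0.0093 (UTR) and 0.0013 to 0.0053 (neither). Of the shifts per pool, CDS in pool 2 passed with quantile normalization (-0.0026), and uncalled shifts changed direction in 11 cases. With cluster means these were -0.00018 (2R, pool 2), -1.9e-07 (3L, pool 2), 0.0014 (3R, pool 1), -0.0026 (X, pool 1) and -0.0021 (X, pool 3). With quantile normalization they were 4.7e-05 (3L, pool 1), -0.0011 (X, pool 1) and -0.0017 (UNKN, pool 3). With log2(intensity + 50) it was 0.00017 and with the 99th percentile cut-off 0.00033 (both 3R, pool 1), and -2.5e-05 for X in pool 1 with the latter. Cluster means could not be formed for the CDS, UTR and neither groups, whose clusters mix these marks. The 3' over 5' ratios moved by less than their SD between pools with quantile normalization. Beyond what is said above, the cause of the changes named here was not tested.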

Other observations

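The comparison by RC and the counts of odd pools were chosen after seeing the data. Among probe sets named by a sequence accession, 68 of 346 with RC in the ID (19.7%) and 41 of 595 without it (6.89%) were detected in all 3 pools. Many accessions have probe sets of both kinds, so the kinds were compared within the 106 accessions with 1 probe set of each. Only the RC probe set was detected for 20 of them and only the other for 1 (exact binomial test on these 21, two-sided, p = 2.10e-05). Of 741 mosquito probe sets with an SD above 0.5 log2, the odd pool lay below the others in 174 cases for pool 1, 191 for pool 2 and 104 for pool 3, and above in 66, 58 and 148 cases.

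A hypothesis was that cluster numbers that follow each other on an arm lie near each other and share regulation or probes. It was written before its test was run. Consecutive detected clusters deviated together slightly, with a mean correlation of 0.027 over 9847 pairs, above the 0.022 at which the central 95% of random orders within arms ended (permutation test, one-sided, p = 0.0032). The central 95% of random orders began at -0.0058. At distances of 2, 3, 5, 10 and 50 clusters it was 0.023, 0.011, 0.013, 0.010 and 0.0075, values examined after the result was seen, of which only that at 2 lay above 0.022. Without probe sets that carry a suffix letter it was 0.025 (p = 0.014, permutation test). The result is consistent with the hypothesis, but whether cluster numbers follow position is not given in the sources used here, and shared regulation was not separated from shared probes.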
